A study of Homo sapiens with 2 samples.

How the data were processed

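Huh7 is an established human hepatocellular carcinoma cell line. Messenger RNA was sequenced from 1 culture carrying a control hairpin (shControl) and from 1 culture carrying a short hairpin RNA against PPIL1, titled shPPIL1#1 and called shPPIL1 here, with 0 libraries of another hairpin against PPIL1 among the labels. The control library is called shControl in its title and WT in its genotype label, and was taken as the control for the hairpin. Per the labels' protocols, polyadenylated RNA was selected from total RNA, fragmented, converted to double-stranded cDNA, ligated to adaptors and amplified by PCR. Genome build hg38 is named per the submitters' processing notes. The aligner, the read counter, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here.

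The authors deposited raw counts per gene, as whole numbers, for 19927 gene rows. Each library was tied to its column through the column name its label gives. The count table held 7 further columns of per-sample counts whose names match no label, and these were used in no step. The authors also deposited FPKM values per gene for each library. In these values, the count divided by the library total and by the FPKM gave a whole-number gene length, within a tolerance of 0.001 bases, for 99.9% of genes with an FPKM above 0 in each library.

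The libraries held 41015345 (shControl) and 41165401 (shPPIL1) counted reads, with 15589 and 15657 genes at 1 read or more. Library sizes were scaled with the TMM factors of edgeR 4.0.16 (R 4.3.3), which were 0.993 for shControl and 1.01 for shPPIL1. A gene was kept when it reached 1 CPM in at least 1 library, which left 12540 genes. Each ratio is the knockdown library over the control library, with an exact 95% interval (Clopper-Pearson on the gene's reads, converted to a ratio with the scaled library sizes). For equal counts of 100 in both libraries this interval reached 1.33-fold, and for equal counts of 1000 it reached 1.09-fold. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals cover counting error only. A library at 0 was to be replaced by a floor of 3 reads, but 0 kept genes needed it. A gene was counted as higher or lower when its ratio was at least 2-fold and its interval excluded 1.

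With 1 library per group, no replicate check was possible, no test between conditions could be made, and no p-value is given. All counts, ratios and percentiles describe these 2 libraries. The comparisons, gene lists and most alternatives were chosen before the data were examined.

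Genes were named by a fixed rule of size. It takes PPIL1, the 15 protein-coding genes per direction whose interval bound nearest to equal expression was most extreme, up to 2 higher and 2 lower members of each described list ranked the same way, and SNW1, CDC40, PRPF8, SF3B1, PPIE and PPIH. Second rows of a symbol are not gene symbols of the reference and were not eligible, though they are counted among the genes kept. Not every gene that the rule takes is named in the text.

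A set of 50 gene lists (44 pathways, complexes and gene groups, and 6 sets of cell type markers) was summarised by the median log2 ratio of the kept members. Each median was placed among those of 10000 random lists of the same size, drawn from the kept genes and matched on mean expression in 20 bins (seed 1). A list was said to stand apart when its median lay outside the central 95% of its random lists. If genes vary independently, about 5% of lists do so by chance, or 2.4 of the 48 lists with at least 3 kept members.

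Gene symbols were matched to NCBI RefSeq (GRCh38.p14), 19811 directly and 80 through a synonym, with 36 unmatched. Exon numbers, transcripts and 3' UTRs came from GENCODE release 29, which uses the same genome build. Near-identical copies were sought by exact matches of 100-base windows, taken every 10 bases of each gene's longest coding transcript, to transcripts of genes elsewhere in the genome. Genes with at least 20% of their windows matched, and second rows of 1 symbol, were treated as sharing reads. Motifs of 6 bases were compared in the 3' UTRs of kept genes other than PPIL1 with at least 400 reads in both libraries together and no shared sequence. For each motif, the mean log2 ratio of the genes that carry it, limited to 1.5 in either direction and taken relative to the median of genes in the same of 50 bins of 3' UTR length, was divided by the error a random set of as many genes would have. The motif was also chosen in a random 5152 of these 10305 genes and tested in the other 5153. That search, and the alternatives without genes that share sequence, without carriers of the motif or with random lists matched on GC content, were added after the data were seen.

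The steps were tested on simulated libraries, with 200 of the genes changed and the rest unchanged. In the simulated comparison of shPPIL1 with shControl, with counting error alone and 12473 genes run, all 100 genes changed 3-fold, all 50 genes changed 8-fold and 0 of 50 genes changed 1.5-fold were called, along with 4 unchanged genes. The interval held the true ratio for 95.0% of genes. With an assumed coefficient of variation of 0.1 between cultures, 9 unchanged genes of 12292 were called, and the interval held the true ratio for only 44.6% of 12491 genes. With 0.2, 274 unchanged genes of 12312 were called, against the 131 calls made in the real libraries. The middle 50% of unchanged log2 ratios ran from -0.15 to 0.15 in the simulation with 0.1 and from -0.28 to 0.29 in that with 0.2. Of 200 unchanged simulated lists of 25 genes, 10 stood apart, and of 20 lists shifted by -0.20, 19 did (12476 genes run). The simulated lists were drawn at random with noise set for each gene separately, so unchanged members did not move together.

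Alternatives were total-count scaling, size factors of DESeq2 1.42.0, upper-quartile factors, FPKM with pseudocounts of 1 and 0.1 (the filter and the counting interval kept), no filter or a filter of 5 CPM, thresholds of 1.5-fold or of an interval wholly beyond 2-fold, an assumed coefficient of variation of 0.1 or 0.2, protein-coding genes alone, list means, other matching of the random lists, and exon numbers of the longest transcript. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.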

Results

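Gene expression was measured by mRNA sequencing in Huh7 hepatocellular carcinoma cells carrying a control hairpin or a hairpin against PPIL1, with 1 library per group. The control library held 41015345 counted reads and the knockdown library 41165401. The design asks how knockdown of PPIL1, a cyclophilin-type prolyl isomerase of the activated spliceosome, alters gene expression in these cells. No difference given here has a replicate check, and "higher" or "lower" refers to the knockdown library against the control library.

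PPIL1 itself was the targeted gene and served as a check of the labels. It had 1505 reads in the control library and 104 in the knockdown library, or 24.2 and 1.67 FPKM. The knockdown library held 6.79% of the control level (95% counting interval 5.51 to 8.29%), a log2 ratio of -3.88 (-4.18 to -3.59). The direction was that of the labels. PPIL1 lies on chromosome 6 from 36854829 to 36874803 (GRCh38) and has 4 exons.

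Few other genes differed by a large factor. Of 12540 genes kept, 66 were at least 2-fold higher and 65 at least 2-fold lower, together 1.04%. At 1.5-fold the counts were 253 and 279. The middle 50% of log2 ratios ran from -0.13 to 0.12, and 95.6% of genes lay within 1.5-fold. In simulated libraries, 274 unchanged genes were called with a coefficient of variation of 0.2 between cultures and 9 with 0.1. The middle 50% of unchanged log2 ratios ran from -0.28 to 0.29 with 0.2 and from -0.15 to 0.15 with 0.1. Both ranges were wider than that of the real libraries. The counts also follow the filter: at 5 CPM or more, 7 genes were higher and 11 lower.

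**Figure D1:**
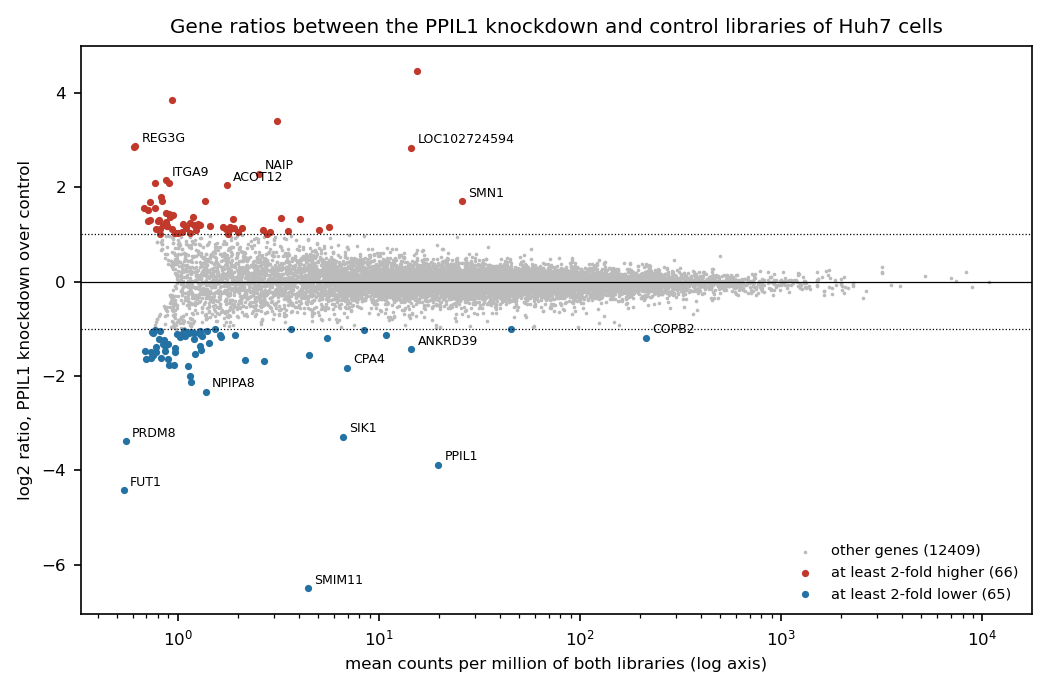
Each point is 1 of the 12540 kept genes, with the mean CPM of both libraries on a log axis and the log2 ratio of the knockdown library over the control library. The 66 genes at least 2-fold higher are red, the 65 at least 2-fold lower are blue, dotted lines mark 2-fold, and PPIL1 sits at -3.88.

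The genes highest in the knockdown library included several with little expression in the control library. REG3G, a secreted antimicrobial lectin, had 6 reads in the control and 45 in the knockdown library, a ratio of 7.37 (3.13 to 21.1). H1-4, a linker histone, stood at 6 and 44 reads in these libraries of polyadenylated RNA, a ratio of 7.20 (3.06 to 20.7). ACOT12, a cytosolic acetyl-CoA hydrolase of liver, was 4.11-fold higher (2.70 to 6.44), and the integrin subunit ITGA9 was 4.46-fold higher (2.42 to 8.86). The Piwi family member PIWIL4 had a ratio of 4.28 (2.37 to 8.29). The Yippee-like genes YPEL4 and YPEL1 had ratios of 4.26 (2.24 to 8.76) and 3.47 (1.93 to 6.63). NR3C2, the mineralocorticoid receptor, was 3.29-fold higher (2.10 to 5.31). KLHL41, a kelch protein of muscle, was 2.53-fold higher (1.93 to 3.35), and the olfactory receptor gene OR1J2 was 3.25-fold higher (1.83 to 6.10). In the 3' UTR, NR3C2, YPEL1 and YPEL4 carried the 6-base motif GATCAT, and in the coding sequence ACOT12, ITGA9 and KLHL41 did. The motif is common. Of 10305 genes with at least 400 reads and no near-identical copy, 28.7% carried it in the 3' UTR. In 5150 of them it stood in neither the 3' UTR nor the coding sequence. The 10 higher genes named in this paragraph shared less than 20% of their sequence with a gene elsewhere.

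Among the 15 lower genes with the most extreme interval bounds, COPB2, the beta-prime subunit of the COPI vesicle coat, was the most abundant, with 12110 reads in the control and 5411 in the knockdown library, a ratio of 0.439 (0.425 to 0.453). ANKRD39, an ankyrin repeat gene, had 862 reads in the control and 325 in the knockdown library, a ratio of 0.370 (0.325 to 0.421). The carboxypeptidase gene CPA4 had a ratio of 0.282 (0.230 to 0.345). IGFBP1, a liver-secreted binding protein of insulin-like growth factors, had a ratio of 0.310 (0.223 to 0.424), and HAL, the histidine ammonia-lyase of histidine breakdown, 0.342 (0.268 to 0.433). FUT1, the fucosyltransferase of the H antigen, had 42 and 2 reads, a ratio of 0.0468 (0.00549 to 0.180). PRDM8 had 41 and 4 reads, a ratio of 0.0959 (0.0249 to 0.265). The receptor phosphatase gene PTPRD and SLFN5, a Schlafen family gene, had ratios of 0.291 (0.170 to 0.478) and 0.295 (0.164 to 0.506). Of these 15 lower genes, PPIL1 included, 5 carried GATCAT in the 3' UTR, namely COPB2, ANKRD39, HAL, SLFN5 and SIK1, the last of which has a near-identical copy. Counting the coding sequence as well, 9 of the 15 lower genes carried it, CPA4, IGFBP1, PTPRD and PPIL1 included, and 8 of the 15 higher genes.

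Genes with near-identical copies took up 5 of the 15 named higher genes and 5 of the 15 named lower genes, and a read from shared sequence matches more than 1 place. They made up 16.8% (exact 95% interval 10.8 to 24.3%) of the 131 genes past 2-fold and 1.83% of all kept genes. The higher ones included LOC102724594, a gene row near-identical in sequence to the splicing factor gene U2AF1 (ratio 7.17, 6.02 to 8.59). They also included NAIP, an inhibitor of apoptosis with GATCAT in its coding sequence (4.88, 3.38 to 7.24). SMN1, whose product assembles spliceosomal snRNPs (3.27, 2.95 to 3.62), and RGPD6 (2.51, 1.97 to 3.22) were among them as well. The lower ones were SMIM11, with 357 and 4 reads, SIK1, a salt-inducible kinase (ratio 0.102, 0.0752 to 0.137), NPIPA8 (0.199, 0.114 to 0.328), NUDT4B (0.249, 0.142 to 0.416) and U2AF1 itself (0.315, 0.218 to 0.448). Summed with its copy, U2AF1 had 279 reads in the control and 1101 in the knockdown library, a ratio of 3.88 in the other direction. How reads that match several copies were treated is not given. The ratio of a single row, such as U2AF1 or LOC102724594, therefore need not measure the expression of a separate gene. Likewise, sums of counted reads need not measure the expression of a family. The sum of SMN1 and SMN2 was 1.93-fold higher, and the sum of SIK1 and its copy 1.45-fold lower. Of 12 families with reads on more than 1 copy, 9 sums lay within 1.5-fold and 3 of those had an interval including 1 (ratios 0.957 to 1.06), that of NPIPA8 included. Each family was chosen for a gene past 2-fold, which favours sums closer to 1. Without genes that share sequence, 55 genes were at least 2-fold higher and 53 lower.

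Proteins of the activated and catalytic spliceosome, the complexes that hold PPIL1, were slightly lower as a group. Of 43 measured genes, 18 were lower with an interval excluding 1, 3 were higher and 22 had an interval including 1. Over all 12540 kept genes, 3316 were lower and 3087 higher with an interval excluding 1. Counts in this and the following lists stand against that background. Of the 43 genes, 0 reached 1.5-fold. The list median was -0.08, at percentile 0.490 of its random lists. PPWD1, a cyclophilin with WD repeats, was 1.40-fold lower and CDC40, a step II splicing factor, 1.34-fold lower, and both carried GATCAT in the 3' UTR, while BUD13 was 1.34-fold higher and CCDC12 1.16-fold higher. Among the spliceosomal partners and relatives named beforehand, SNW1, which binds PPIL1, had a ratio of 0.941 (0.904 to 0.980), PRPF8 0.911 (0.887 to 0.936), SF3B1 0.954 (0.938 to 0.970) and PPIH 1.09 (1.00 to 1.17). PPIE had a log2 ratio of -0.07 (-0.17 to 0.03). Of these, PRPF8, SF3B1 and PPIE carried the motif in the coding sequence. Left without the genes that carry GATCAT in the 3' UTR or the coding sequence, the list's 21 remaining members had a median of -0.02 and no longer stood apart.

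Other splicing lists lay within the range of random lists. The median was -0.06 for the U2 snRNP and SF3A/SF3B proteins (percentile 6.42), -0.02 for the Sm and U1/U4/U6 snRNP proteins (39.5), -0.07 for the other cyclophilins (8.62), -0.07 for the SR proteins and splicing kinases (3.70) and -0.07 for the hnRNP proteins (5.20). Individual members still differed, and USP39, a tri-snRNP protein, was 1.34-fold lower, SRSF7 1.28-fold lower, TRA2B 1.26-fold lower, PPIG 1.29-fold lower and SYNCRIP 1.31-fold lower. All of these but SRSF7 carried GATCAT in the 3' UTR or the coding sequence. Of the 10305 genes searched for the motif, 5150 carried it in neither part, so carriers are common. Of 23 listed snoRNA host and NMD-sensitive transcripts, 8 were measured. Their median was -0.19 (percentile 0.430), with ATF3 1.27-fold and UPP1 1.27-fold lower. ATF3 also belongs to the lists of the ATF4-driven stress response and of immediate-early genes. The host genes GAS5, SNHG1 and ZFAS1 were not among the genes of the count table. Of its 19927 rows, 19882 are protein-coding genes, so the list says little about snoRNA hosts. The list did not stand apart without the carriers of GATCAT in the 3' UTR or coding sequence (median -0.14).

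The lists of MYC targets, of the ATF4-driven stress response and of immediate-early genes were lower. The MYC target and ribosome biogenesis list had 27 of 32 measured genes lower with an interval excluding 1 and 0 higher, with a median of -0.24, below all of its random lists (percentile 0.00). MYC itself was 1.66-fold lower (ratio 0.604, 0.581 to 0.628) and DKC1, the pseudouridine synthase dyskerin, 1.30-fold lower. In the ATF4-driven integrated stress response list, 23 of 31 genes were lower and 3 higher, with a median of -0.23 (percentile 0.00). CTH, the cystathionine gamma-lyase, was 1.66-fold lower and CHAC1, a glutathione-degrading enzyme, 1.47-fold lower, whereas PSPH and NUPR1 were 1.14-fold and 1.19-fold higher. Immediate-early and AP-1 genes had 19 of 29 lower and 4 higher, with a median of -0.25 (percentile 0.00). Within that list the AP-1 subunits FOSB and FOS were 2.30-fold and 1.94-fold lower, and BTG2 and IER5 were 1.51-fold and 1.40-fold higher. Of these genes CTH, FOS and IER5 carried GATCAT in the 3' UTR, and CHAC1 and DKC1 in the coding sequence. Without the carriers in either part the medians of the stress response and immediate-early lists were both -0.16 (20 and 21 genes left), and both still stood apart.

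Lists of lipid synthesis genes had lower medians, by smaller factors. Of 25 cholesterol synthesis and uptake genes, 23 were lower and 0 higher, with a median of -0.15 (percentile 0.00). MVD, the mevalonate diphosphate decarboxylase, was 1.38-fold lower. Fatty acid and triglyceride synthesis genes had 16 of 24 lower and 4 higher, with a median of -0.12 (percentile 0.0900). The desaturase genes FADS2 and SCD were 1.30-fold and 1.20-fold lower, while ACACB and DGAT2 were 1.44-fold and 1.32-fold higher. Taken by its mean (-0.08) instead of its median this list did not stand apart, nor did it without the carriers of GATCAT in the 3' UTR or coding sequence (median -0.09, 9 genes left). NRF2 and ferroptosis-defence genes had 16 of 28 lower and 3 higher (median -0.10, percentile 0.560), with AKR1B10 2.22-fold lower, the cystine transporter gene SLC7A11 1.27-fold lower and HMOX1, the inducible heme oxygenase, 1.30-fold higher. Its median was 0.02 without the carriers of that motif, with 11 genes left, and it did not stand apart, nor did it without the carriers in the 3' UTR alone (median -0.04). Among the lower genes FADS2 and SCD carried the motif in the coding sequence and SLC7A11 in the 3' UTR, and among the higher genes ACACB carried it in the coding sequence and DGAT2 in the 3' UTR.

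Lists of mitochondrial genes and of hepatocyte secretion had higher medians. All 13 mitochondrially encoded genes were higher with an interval excluding 1, with a median of 0.20, above all of its random lists, led by ND3 (1.29-fold) and ND4 (1.24-fold). They took 2.43% of reads in the control library (exact 95% interval 2.42 to 2.43%) and 2.85% in the knockdown library (2.85 to 2.86%). Nuclear genes of the respiratory chain had 18 of 39 higher and 8 lower (median 0.05, percentile 99.3), with UQCRB 1.16-fold higher and NDUFA1 1.21-fold higher, against SDHB, which was 1.21-fold lower. Secreted plasma proteins of hepatocytes had 21 of 34 higher and 5 lower (median 0.09, percentile 99.96), and the median ran from 0.06 at 5 CPM or more to 0.13 without the carriers of GATCAT in the 3' UTR or coding sequence. Among them ITIH1, a hyaluronan-binding inhibitor subunit, was 2.25-fold higher and the fibrinogen chain FGA 1.28-fold higher, while AHSG was 1.17-fold lower. ORM1, 1.29-fold lower, shares sequence with a near-identical copy. In the coding sequence, the higher gene FGA and the lower gene SDHB carried GATCAT. The 8 hepatocyte markers had a median of 0.09 (percentile 99.3), with FGB 1.18-fold and APOA2 1.11-fold higher. All of these markers but HNF4A also belong to the list of secreted plasma proteins, so the lists are not independent. Without the carriers of GATCAT in the 3' UTR or coding sequence the 6 markers left had a median of 0.10. They did not stand apart, so the call was lost but the shift was not smaller.

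Lists of interferon, inflammatory and lysosomal genes also had higher medians. Interferon-stimulated genes had 16 of 29 higher and 3 lower (median 0.16, percentile 99.99), led by the chemokine CXCL10 (1.72-fold) and the guanylate-binding protein GBP1 (1.44-fold), while MX2 and OAS1 were 1.23-fold and 1.22-fold lower. NF-kappaB and inflammatory genes had 12 of 22 higher and 2 lower (median 0.14, percentile 99.98), with the cytokine signalling suppressor SOCS3 1.51-fold and IL32 1.32-fold higher and the adhesion molecule ICAM1 and the chemokine CXCL1 1.25-fold and 1.22-fold lower. Antigen presentation genes had 8 of 15 higher and 0 lower (median 0.16, percentile 98.8), among them the immunoproteasome subunit PSMB9 (1.26-fold) and the peptide transporter TAP2 (1.20-fold). Autophagy and lysosome genes had 18 of 33 higher and 2 lower (median 0.07, percentile 99.4), with the sialidase NEU1 and the protective protein CTSA 1.24-fold and 1.22-fold higher and MAP1LC3B 1.30-fold lower, and a median of 0.12 without the carriers of GATCAT in either part. Epithelial-mesenchymal and extracellular matrix genes (median 0.12, percentile 99.8, 11 of 25 higher and 5 lower) included the urokinase PLAU at 1.37-fold and vimentin, VIM, at 1.24-fold higher, and the integrin subunit ITGA2 at 1.46-fold lower. YAP and TEAD target genes (median 0.13, percentile 99.2, 7 of 17 higher and 2 lower) included AMOTL2 at 1.19-fold and NT5E at 1.18-fold higher, and AJUBA at 1.45-fold lower. The antigen presentation list did not stand apart by its mean (0.14), without the carriers of GATCAT in the 3' UTR (median 0.15, 10 genes left) or without carriers in either part (0.16, 9 left), with shifts close to that of the full list. Without carriers in either part the extracellular matrix list (0.14, 11 left) and the YAP list (0.14, 12 left) did not stand apart either, though their medians were not smaller. Their shifts were smaller by their means (0.03 and 0.05) and without a filter on low counts (0.07 and 0.10), as was that of the YAP list with log2(FPKM + 1) (0.08), and they did not stand apart there. Among the lower genes AJUBA, MAP1LC3B and CXCL1 carried the motif in the 3' UTR and MX2 in the coding sequence, and among the higher genes CXCL10 and NEU1 carried it in the coding sequence.

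**Figure D2:**
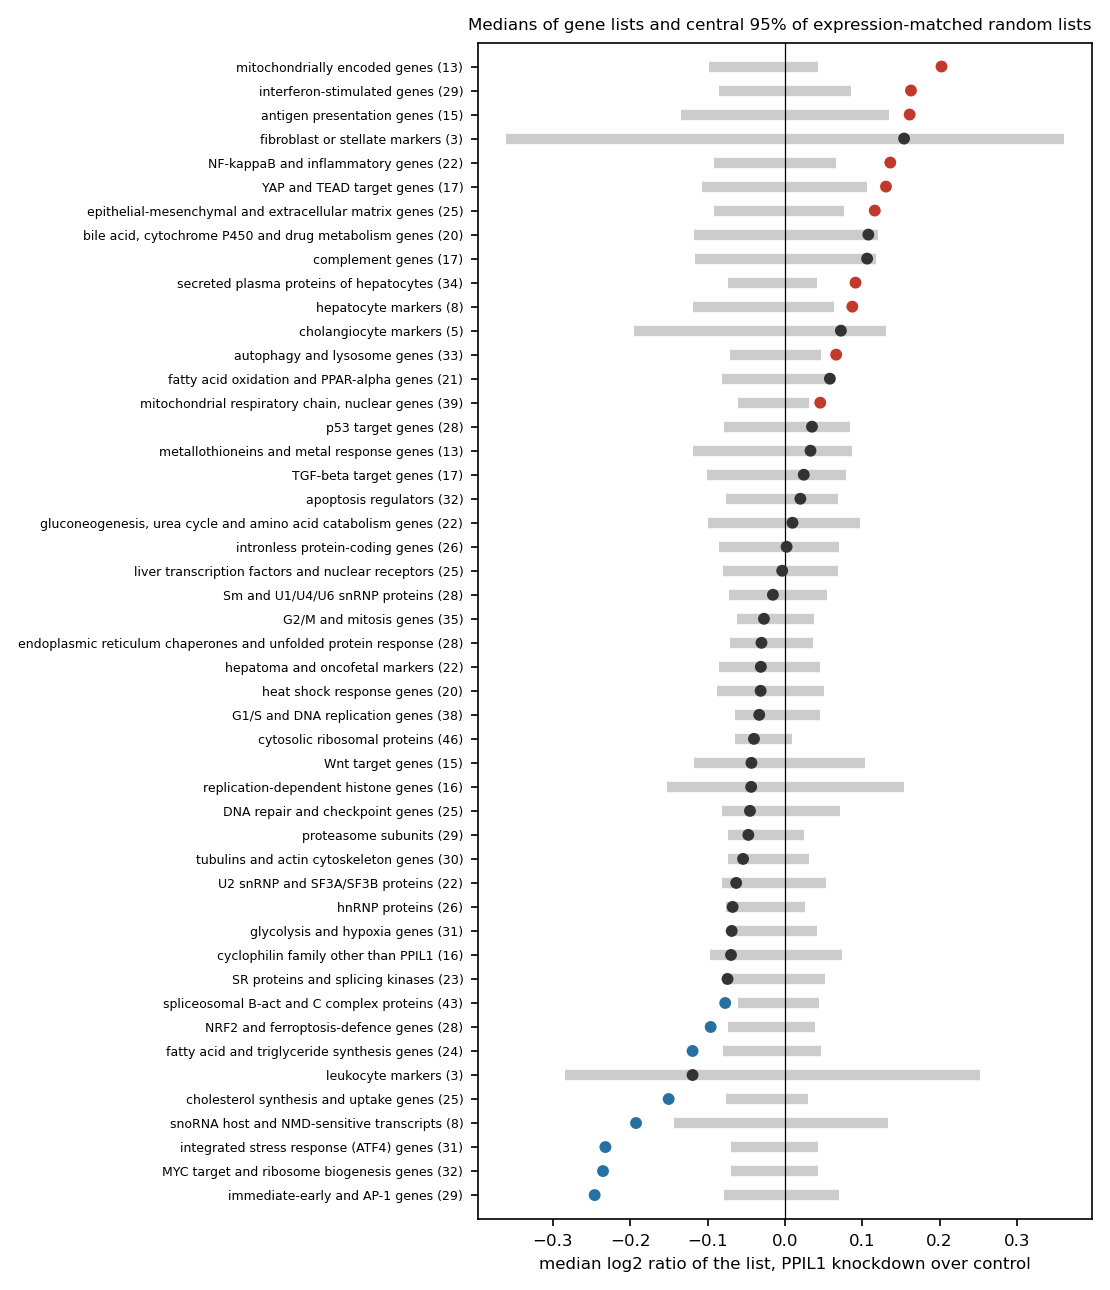
Points are the median log2 ratios, knockdown over control, of the 48 lists with at least 3 measured genes (number measured in brackets), and grey bars are the central 95% of 10000 expression-matched random lists. The 8 blue points lie below their bars, from -0.25 to -0.08, and the 10 red points above, from 0.05 to 0.20.

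In all, 18 of 48 lists stood apart, 8 lower and 10 higher, where about 2.4 would if genes varied independently. Members of a list can move together between any 2 cultures and some lists share members, so the number by chance is not known. The lists of cell division did not stand apart. The median was -0.03 for G2/M and mitosis genes (percentile 26.4), -0.03 for G1/S and DNA replication genes (18.8) and -0.05 for DNA repair and checkpoint genes (14.1), with CENPA 1.31-fold higher and PLK1 1.15-fold lower. Medians for p53 targets (0.035, percentile 79.0), apoptosis regulators (0.02, 72.9) and replication-dependent histone genes (-0.04, 24.0) were also inside the range. Polyadenylated RNA was selected, so histone transcripts without a poly(A) tail are poorly covered. The protein quality control lists were likewise inside, at -0.03 for endoplasmic reticulum chaperones (30.4), -0.03 for heat shock genes (33.6) and -0.05 for proteasome subunits (14.2), although XBP1, a transcription factor of the unfolded protein response, was 1.27-fold lower. Cytosolic ribosomal proteins had a median of -0.04 (22.3).

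Further metabolic and hepatic lists within the range of random lists were fatty acid oxidation (0.06, percentile 97.4), complement (0.11, 96.1), bile acid and cytochrome P450 genes (0.11, 95.9), gluconeogenesis and the urea cycle (0.01, 59.0), liver transcription factors (-0.0035, 51.6), glycolysis and hypoxia (-0.07, 2.94), hepatoma and oncofetal markers (-0.03, 33.7) and metallothioneins (0.03, 85.0). Within them C1S was 1.66-fold higher, SULT2A1, a sulfotransferase of bile acids and steroids, 1.41-fold higher, the collagen cross-linking enzyme LOX 1.53-fold lower and the carbonic anhydrase CA12 1.73-fold lower. TGF-beta targets (0.02, 77.2), Wnt targets (-0.04, 23.9), tubulins and actin cytoskeleton genes (-0.05, 9.95) and intronless genes (0.0022, 60.2) did not stand apart, although BMP4, a ligand in the TGF-beta and Wnt lists, was 2.04-fold lower and ACTB 1.28-fold lower. The motif GATCAT stood in the 3' UTR of the higher gene C1S and of the lower gene BMP4, and in the coding sequence of ACTB. Markers of other cell types gave no list that stood apart. The medians were 0.15 for 3 fibroblast or stellate markers (percentile 81.8), -0.12 for 3 leukocyte markers (18.4) and 0.07 for 5 cholangiocyte markers (88.0). COL3A1, a fibrillar collagen, had 16 reads in the control and 48 in the knockdown library. Of the endothelial markers only PECAM1 passed the filter, at 410 and 352 reads and with GATCAT in its coding sequence, and of the erythroid markers 0 did.

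Genes with few and many introns had medians close to equal expression. Median log2 ratios were 0.0085 for 197 intronless genes, -0.0035 for 947 genes with 1 to 2 introns, 0.005 for 2661 with 3 to 5, -0.0072 for 3577 with 6 to 10 and -0.002 for 5053 with more than 10. The middle 50% of the intronless genes ran from -0.18 to 0.19 and that of genes with more than 10 introns from -0.12 to 0.11. Across quartiles of gene length the medians lay between -0.02 and 0.01. These values are across genes, which are not independent replicates, and gene counts carry no measure of intron retention or splice site choice.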

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

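The alternatives without genes that share sequence, without carriers of GATCAT and with random lists matched also on GC content were chosen after the data were seen. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Total-count scaling, DESeq2 size factors and upper-quartile factors shifted every log2 ratio by 0.02, 0.0036 and 0.0075, and gave 66 to 68 genes at least 2-fold higher and 62 to 65 lower. The counts of higher and lower genes moved with the unit, filter and threshold. They were 4 and 8 with log2(FPKM + 1), 32 and 27 with log2(FPKM + 0.1), 337 and 319 without a filter, 7 and 11 at 5 CPM, 253 and 279 at 1.5-fold, and 13 and 15 with intervals wholly beyond 2-fold. A pseudocount shrinks ratios of low genes and a stricter filter tests fewer genes by construction. An assumed coefficient of variation of 0.2 left 62 and 61. That setting only widens the interval, by less than the 2-fold already required except at low counts. Most calls therefore passed by construction, and the counts do not show that the calls exceed variation between cultures. In the simulation with 0.2, 274 unchanged genes of 12312 were called. The PPIL1 log2 ratio was -3.24 with log2(FPKM + 1), for the same reason, and inside its counting interval otherwise. Of 620 list values, 579 kept the main call, whether standing apart on the same side or not standing apart. Of the rest, 16 lost the call, 24 gained it and 1, of a list that stood apart, changed direction. Direction was not compared where a list did not stand apart. Of 18 lists that stood apart, 10 did so under all 13 alternatives, 4 lower and 6 higher. The median of NRF2 and ferroptosis-defence genes was 0.0189 without carriers of GATCAT in the 3' UTR or coding sequence, and the cause was not tested. Of 1030 values of 206 named genes, 964 stayed inside the gene's counting interval, 66 moved and 0 changed direction.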

Other observations

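The tests of the summed counts of gene families and of their other copies, of GATCAT and of motifs with the same bases in genes not used to choose it, of the motif ranks across coding sequences, of random lists matched on GC content and of lists without carriers of GATCAT were chosen only after the result was seen, and the motif search itself was not planned.

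Median log2 ratios per chromosome were close to equal expression. Over the 23 nuclear chromosomes tested, the medians lay between -0.04 for chromosome 13 and 0.03 for chromosome 18, against 0.20 for the 13 mitochondrial genes. Several abundant genes outside the lists were lower by close to 2-fold and were picked out after their values were seen. TBL1X, a subunit of NCoR corepressor complexes, was 2.01-fold lower, CANT1, a calcium-activated nucleotidase, 1.94-fold, ADPGK, an ADP-dependent glucokinase, 1.95-fold, the adaptor gene CRKL 1.88-fold, TIMM17A, an inner membrane import subunit of mitochondria, 1.92-fold, and DDX21, a nucleolar RNA helicase, 1.80-fold lower.

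Those genes carry the motif GATCAT in their 3' UTR, and among 10305 genes with at least 400 reads and no near-identical copy, GATCAT gave the lowest standardised shift of all 4096 6-base motifs in 3' UTRs (-8.54, next lowest -6.30). Chosen again in a random 5152 of these genes, where GATCAT was also lowest, it was lowest in the other 5153 as well (-5.43), and there a candidate explanation is a seed-type off-target effect of the hairpin, as 41.5% of the 41 genes at least 1.5-fold lower carried it in the 3' UTR (length-matched draws 14.6 to 36.6%), against 3 of the 23 higher genes (draws 4.35 to 34.8%). Base composition is argued against as the whole cause, since in those 5153 genes the other 179 motifs with the same bases reached -3.19 at the lowest. The shift was not limited to the 3' UTR. Genes with the motif in the coding sequence alone were shifted by -0.0474, those with it in the 3' UTR alone by -0.0510. The difference of 0.0036 was 0.57 of its standard error. A property of the gene or of its sequence would also give similar shifts in both parts. These values do not tell it from a seed-type effect. Among 7346 genes without GATCAT in the 3' UTR, it was again lowest of 4096 coding motifs (-8.89, next lowest -7.49). The mean shift was -0.035 with 1 site in the 3' UTR and -0.042 with 2 or more. PPIL1 has the motif 1 time, in its coding sequence, but the hairpin's sequence is not given in the sources used here, so pairing with the hairpin stays a hypothesis, as does a response of such genes to loss of PPIL1, which was not tested.

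Genes with near-identical copies took 16.8% of the genes past 2-fold and 1.83% of all kept genes. Whether reads were traded between listed copies stays open, since the copies other than the most changed one moved the opposite way, with an interval excluding 1, in 41.7% of 12 families with reads on more than 1 copy, or 5, and the same way in 4, while 9 of the 12 sums lay within 1.5-fold, which the choice of each family for a gene past 2-fold favours. Trading alone is argued against in the U2AF1 and SMN1 families, whose summed log2 ratios both had intervals at least 0.84 from 0. Reads that match several places could also have been kept or dropped differently in the libraries. Log2 ratios of the 52 genes with at least 80% shared sequence had an SD of 1.33. It was 0.27 to 0.86 in 1000 expression-matched sets without shared sequence. That wider spread restates the excess of such genes past 2-fold, and any cause of the excess would give it. It therefore cannot decide between causes. An effect of the knockdown on these families stays open and untested.

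The lists of MYC targets, ATF4-driven stress response, immediate-early, cholesterol and fatty acid synthesis genes were lower together and share few members (139 genes, 2 of them in more than 1 list). GC content and length bias is argued against, since 5 of the 5 lists stayed below the central 95% of random lists matched on expression, length and GC content. A seed-type off-target effect of the hairpin acting on the list members themselves is also argued against as the whole cause. Of the 139 genes, 26 carried GATCAT in the 3' UTR, and 5 of 5 lists stayed below without such genes. Once carriers in the coding sequence were left out too, 4 of 5 stayed below. The stress response median then moved from -0.23 to -0.16 and the immediate-early median from -0.25 to -0.16, so a part in these lists stays open. These values do not exclude an off-target effect on a shared regulator. A difference between the 2 cultures other than the knockdown cannot be told apart from an effect of PPIL1, with 1 library per group.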
